A study of Mus musculus with 42 samples.

How the data were processed

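Gene expression was measured with Affymetrix MOE430.2 arrays in 42 deposited columns, 25 of Purkinje and 17 of Stellate/Basket cells from Gad67-GFP G42 mice. Per the labels, cells were released from cerebellar slices with protease and trituration in the presence of channel and receptor blockers, picked by hand, and their polyadenylated RNA was amplified in 2 rounds. The deposited values are log2 expression per probe set, normalized by the authors. The submitters' processing notes name R 2.9.1 and GCRMA, and the role and order of these tools are not given in the sources used here. Values run from 3.94 to 14.6. Array medians ran from 5.91 to 6.16 and the 90th percentiles from 8.55 to 9.49, so the arrays share a centre more closely than an upper range. No detection calls come with the values, so folds against groups near the low end of the scale are uncertain. The number of arrays limits the precision.

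Each column was tested against the mean of each pair of other columns of its group. 2 of the 42 columns equal such a mean in every probe set, within 1e-08: Stellate/Basket P35 replicate 3 and P56 replicate 2. They were left out as averages of other columns, which leaves 40 arrays, 15 of them from Stellate/Basket cells. The series' design text gives 3 biological replicates, while several groups hold 4 columns, and the columns were used as labelled.

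In the annotation used, 34958 probe sets carried 1 gene symbol, 932 carried several and 9211 none. Only those with 1 symbol were used. A gene was represented by its probe set with the highest mean over the arrays, which gave 18194 genes, 9012 of them with more than 1 probe set. Genes with a log2 value above 5 in at least 3 arrays were kept, 17478 in all. The log2 values were not scaled further.

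Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per cell type and age over the 12 groups and moderated variances. P-values were adjusted by the Benjamini-Hochberg method over the 17478 genes within each comparison. A gene was called when its adjusted p was under 0.05 and its absolute log2 difference at least 1. The comparisons were the cell type difference averaged over the 5 shared ages, the difference at each of these ages, the Purkinje change from P3 to P56 and from P14 to P56, the Stellate/Basket change from P14 to P56, each step between successive ages, and the difference between the cell types in the change from P14 to P56. F tests covered the 7 Purkinje and the 5 Stellate/Basket ages. Log2 differences are Purkinje minus Stellate/Basket cells, or the later minus the earlier age. Expected overlaps assume that calls in the 2 lists are independent. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

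29 gene lists, 9 of cell type markers and 20 of functional groups, were tested in the 5 main comparisons with camera from limma, with a preset correlation between genes of 0.01, and again with an estimated correlation. Adjustment was over the 29 lists in each comparison. The lists hold 529 genes, of which 467 were measured. Lists overlap: 9 of 18 Purkinje markers, 2 of 11 interneuron markers, 4 of 15 granule cell markers, 1 of 7 Golgi and unipolar brush cell markers and 6 of 16 mGluR1 signalling genes also stand in another list, and 0 of 12 astrocyte and Bergmann glia markers do.

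The comparisons, gene lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. Named were the 12 genes with the largest called difference in each direction between the cell types whose ages all differed the same way, the 10 largest in each direction for Purkinje P3 to P56 and the 8 largest for each change from P14 to P56 among genes whose arrays did not overlap, the 8 largest for the difference between changes, and the 3 largest for each age and step. Up to 4 called members of each list were added, or the 2 with the largest values where fewer than 2 were called. Gad1, Pcp2, Calb1 and Kit were reported as checks of the sort. Symbols made of clone, model or predicted locus names were counted and not named.

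Alternatives covered the filter on dim genes, the summary of probe sets, the variance model, array weights, a block of replicate number, centring and quantile normalization, the thresholds, the arrays in the fit, and leaving out each array in turn. The 42 deposited columns, the level of Xist and the 90th percentile of each array as covariates, and P35 as the last or P14 as the first age were added after the data were seen.

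The procedure was tested on simulated data with changes of known size. Of genes changed by a log2 value of 1.5, 2 and 3, it recovered 100%, 100% and 100% for the cell type difference, 92.5%, 95.5% and 100% for Purkinje P3 to P56, 94%, 98.5% and 100% for Purkinje P14 to P56, 85.1%, 98.5% and 100% for Stellate/Basket P14 to P56, and 61.2%, 77.6% and 97% for the difference between these changes. In each of the 10 comparisons simulated, 200 of 17478 genes were changed, and at most 6 of the others were called. The simulated noise was independent between genes and arrays, with 1 spread per gene in all groups. These rates therefore do not cover groups with a larger spread, such as Stellate/Basket P56.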

Results

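Gene expression was measured on whole-genome arrays in hand-sorted mouse Purkinje cells, the output neurons of the cerebellar cortex, and Stellate/Basket cells, the inhibitory interneurons of its molecular layer. The cells came from Gad67-GFP G42 mice, a transgenic line in which inhibitory neurons carry green fluorescent protein, and were picked by fluorescence and soma size. Purkinje cells were taken at postnatal day 3 (P3), P7 and P14 with 3 arrays each, and at P21, P28, P35 and P56 with 4 arrays each. Stellate/Basket cells were represented by 4 arrays at P14, 3 at P21, 4 at P28, 2 at P35 and 2 at P56. At P35 and at P56, 1 further Stellate/Basket column equals the mean of the other columns of its age in every probe set, within 1e-08, and these 2 columns were left out. The 40 arrays used carried deposited log2 values between 3.94 and 14.6, with array medians between 5.91 and 6.16. The labels call the replicates biological, so the p-values measure the spread between samples, pooled over the 12 groups, and the number of arrays limits the precision. At Stellate/Basket P35 and P56, with 2 arrays each, this assumes a spread like that of the other groups.

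Of the genes used to check the sort, Calb1, Pcp2 and Kit differed between the cell types. Gad1, which encodes a GABA-synthesising enzyme, was at log2 12.38 in Purkinje and 12.49 in Stellate/Basket arrays, a difference of -0.11 ± 0.07 (SE) that did not pass the test (adjusted p = 0.181). Calb1, a calcium buffer of Purkinje cells, was higher in Purkinje arrays by 3.58 ± 0.44 (SE), and Pcp2, a Purkinje cell marker, by 1.58 ± 0.22. Kit, a receptor tyrosine kinase of molecular layer interneurons, was lower in Purkinje arrays by a log2 difference of -4.28 ± 0.13. The Purkinje arrays at P3 and P7 and the Stellate/Basket arrays at P56 stood furthest from this pattern. In Purkinje arrays, the mean of the interneuron markers was 9.58 ± 0.09 (SD, n = 3) at P3 and 9.42 ± 0.47 (n = 3) at P7, against 6.12 at P14, while the mean of the Purkinje markers was 7.94 ± 0.87 at P3 and 12.21 at P14. In Stellate/Basket arrays, the interneuron markers went from 10.30 at P14 to 6.56 ± 0.12 (SD, n = 2) at P56, and the Purkinje markers from 8.33 to 10.87 ± 1.10. The Purkinje markers in these cells were already at 9.12 at P21, 9.75 at P28 and 9.57 at P35. Astrocyte and Bergmann glia markers in Stellate/Basket arrays had a mean of 7.30 at P14, 9.41 at P21 and 10.63 at P56.

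**Figure D1:**
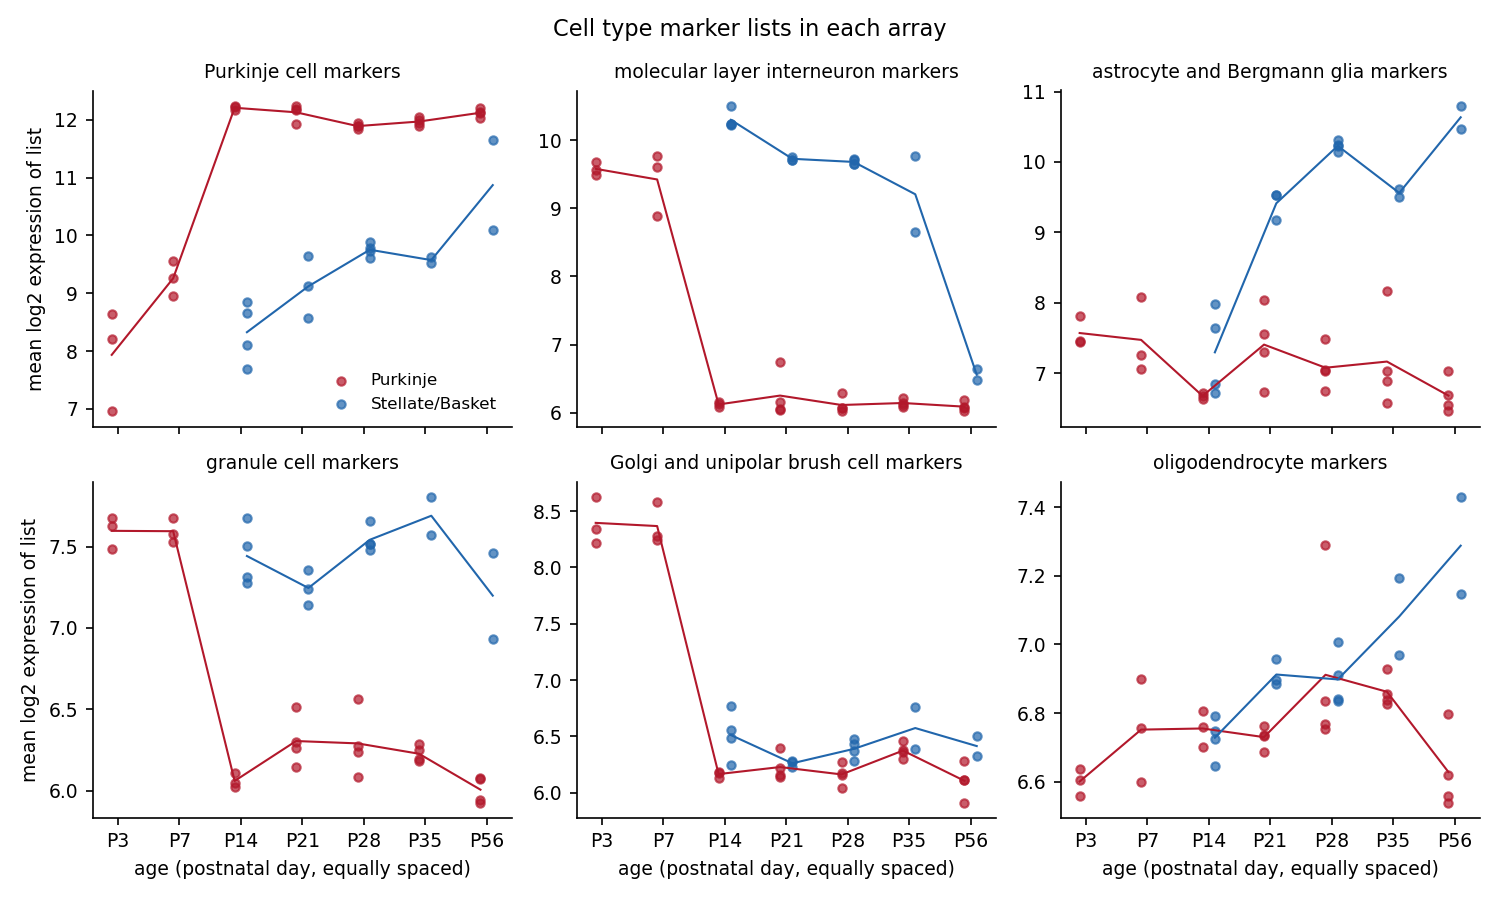
Mean log2 value of 6 cell type marker lists (vertical axis) against postnatal day (horizontal axis), with 1 point per array and lines through the group means of Purkinje and Stellate/Basket cells. The interneuron markers are high in Purkinje arrays at P3 and P7 and low in Stellate/Basket arrays at P56, where the Purkinje markers reach a mean of 10.87.

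The first question was which genes distinguish Purkinje from Stellate/Basket cells when the 5 shared ages are averaged with equal weight. Among genes with the same direction at all 5 ages, the largest difference toward Purkinje cells was that of Stk17b (1450997_at), a serine/threonine kinase, at a mean of 12.15 against 7.08, a 33.6-fold difference (log2 5.07 ± 0.19, SE; adjusted p = 1.16e-20). Slc1a6 (1418933_at), the Purkinje cell glutamate transporter, was higher by 4.35 ± 0.19 and the kainate receptor subunit Grik1 by 4.62 ± 0.23. Largest toward Stellate/Basket cells was Zic1 (1423477_at), a zinc finger transcription factor, at 11.98 against 5.79 (log2 -6.19 ± 0.21; adjusted p = 1.09e-21). Also among the 12 leading Stellate/Basket genes were the cannabinoid receptor Cnr1 (1434172_at; -5.76 ± 0.20), Btbd11 (-5.51 ± 0.12) and protein kinase C beta, Prkcb (-5.03 ± 0.09). Cep76, Klhl4, Rasl11b, Smpx, Nell1, Ptprr, Bcl11a and Plxdc1 were also among the 12 leading Purkinje genes, with log2 differences from 4.37 to 4.96. Cnpy1, Megf10, Tcf4, Slc24a3, Tmsb4x, Fam107a, Nfib and Cnn3 completed the 12 leading Stellate/Basket genes, from -4.89 to -5.57. In all, 2009 of 17478 genes were called, 1113 higher in Purkinje and 896 higher in Stellate/Basket cells. After quantile normalization these were 959 and 981, and with P35 as the last age 1051 and 1080. At every one of the 5 ages, 392 genes were called higher in Purkinje cells and 183 higher in Stellate/Basket cells. At every age from P14 to P35, without P56, 531 were called higher in Purkinje and 501 higher in Stellate/Basket cells. In opposite directions at 2 ages, 295 genes were called.

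Among the marker lists, 12 of 13 measured Purkinje markers were higher in Purkinje cells, with a median log2 difference of 2.22 (camera adjusted p = 1.51e-09, and 0.0314 with an estimated correlation). Casq2, a calcium-store protein (4.31), and Ppp1r17 (3.96), a phosphatase inhibitor, were the largest after Slc1a6. Of the interneuron markers, 7 of 9 were lower in Purkinje cells and none was higher (median -3.21; camera adjusted p = 5.28e-10, and 0.00158 with an estimated correlation), among them Ptprk (-4.39), Lypd6 (-4.25) and the transcription factor Tfap2b (-3.54). 9 of 12 astrocyte and Bergmann glia markers were also higher in Stellate/Basket arrays (median -2.99; camera adjusted p = 1.30e-07, and 0.044 with an estimated correlation), led by the gap junction protein Gja1 (-4.87), Gdf10 (-3.97) and the water channel Aqp4 (-3.92). 6 of 14 granule cell markers lay in the same direction (median -0.56; camera adjusted p = 5.92e-05, and 0.00876 with an estimated correlation), with Neurod1 at -3.91, Cbln3 at -1.79 and Gabra6 at -1.47.

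Among the functional lists, genes of mGluR1, calcium store and protein kinase C signalling were higher in Purkinje cells, with 7 of 12 called (median 1.98; camera adjusted p = 1.49e-06, and 0.044 with an estimated correlation), including the ryanodine receptor Ryr1 (4.19) and the phospholipase Plcb3 (2.46). GABA-A receptor subunits were lower, with 4 of 10 called (median -0.69; camera adjusted p = 7.85e-04, and 0.0314 with an estimated correlation), led by Gabra2 (-3.29) and Gabrb1 (-2.40). Axon guidance genes were lower in Purkinje cells as a list (median -0.21; camera adjusted p = 0.00448, and 0.0314 with an estimated correlation), although 6 of the 49 were higher and 12 lower. Sema3e, a semaphorin, was at -3.07 and the netrin receptor gene Neo1 at -2.86, against 3.76 for the ephrin receptor Epha5. 5 further list calls were lost with an estimated correlation. Neurite growth genes were lower in Purkinje cells (10 of 20, 2 higher; median -0.90; camera adjusted p = 1.52e-04, and 0.0564 with an estimated correlation), with Gap43 at -3.19. Immediate early and stress genes were lower (8 of 19, 1 higher; median -0.74; camera adjusted p = 3.98e-04, and 0.0783 with an estimated correlation), with Egr1 at -2.40 and the opposite direction for the chaperone Hspa5 (1.45). Ribosomal protein genes were lower (2 of 24; median -0.60; camera adjusted p = 7.29e-07, and 0.105 with an estimated correlation), and oxidative phosphorylation genes higher (1 of 29; median 0.20; camera adjusted p = 0.0292, and 0.54 with an estimated correlation). Ionotropic glutamate receptors were called lower (5 of 16, 2 higher; median -0.07; camera adjusted p = 0.0467, and 0.0774 with an estimated correlation), with Gria4 at -4.78 and Grik1 opposite. This list was not called with array weights (-0.05), a block of replicate number (-0.07), all 42 columns (-0.07) or Xist as a covariate (-0.08). The glutamate receptor list (-0.04) and oxidative phosphorylation (0.19) were not called with P35 as the last age, nor with the 90th percentile of each array as a covariate (-0.05 and 0.20). Without Stellate/Basket P56 replicate 3 neither was called (-0.08 and 0.17), and the glutamate receptor list was also not called without Purkinje P14 replicate 2 (-0.06) or 3 (-0.07), P28 replicate 2 (-0.06), P35 replicate 3 (-0.07) or 4 (-0.07), or without Stellate/Basket P14 replicate 4 (-0.06), P21 replicate 2 (-0.07) or P56 replicate 1 (-0.11). The number of called members was the same in each of these lists when adjusted over the list alone. With a gene taken as the mean of its probe sets, 1332 genes were called in place of 2009. At P14, P21, P28, P35 and P56 the median difference of the astrocyte and Bergmann glia markers was -0.94, -2.32, -3.77, -3.14 and -4.17. Beside it, that of GABA-A receptor subunits was -0.36, -0.74, -1.01, -0.56 and -1.03, and that of immediate early and stress genes -0.19, -0.72, -1.17, -0.92 and -0.60. The Stellate/Basket P56 arrays, with their raised Purkinje markers, are 1 of the 5 ages averaged, and with P35 as the last age 2131 genes were called, 1778 of them shared. The Purkinje markers in Stellate/Basket arrays were also higher at P35 than at P14 (mean 9.57 against 8.33).

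**Figure D2:**
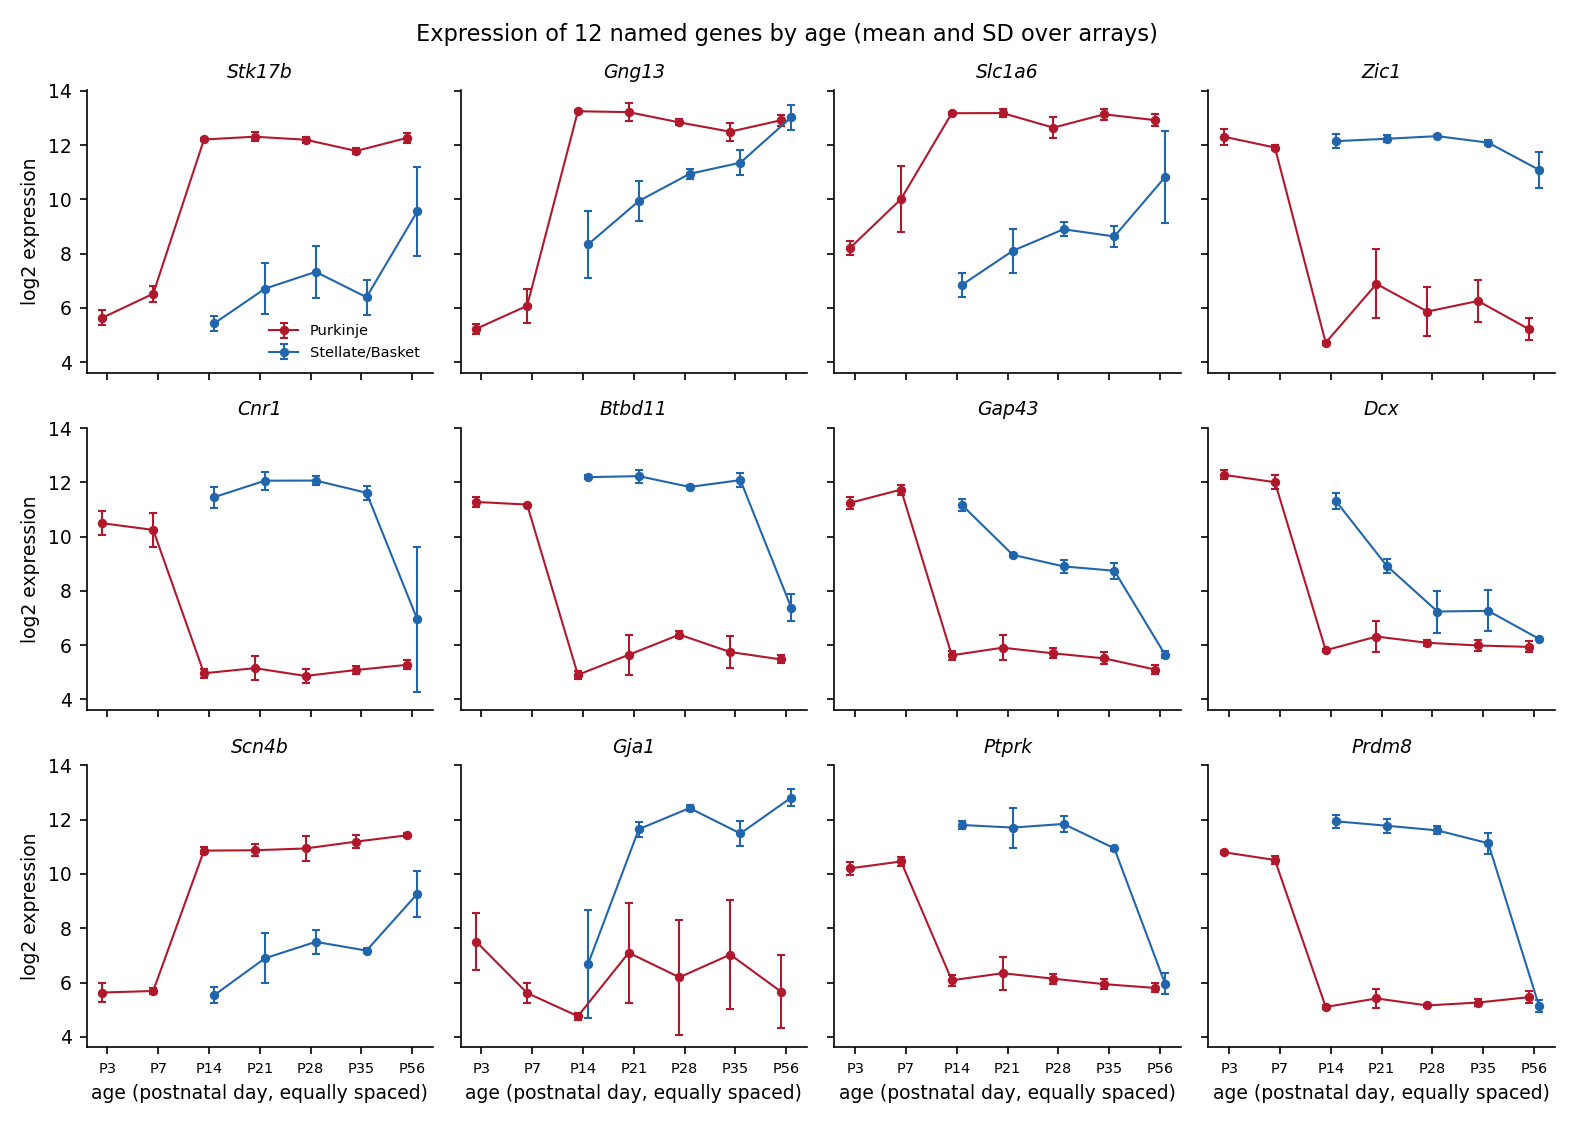
Log2 value (mean ± SD; vertical axis) of 12 genes against postnatal day in Purkinje and Stellate/Basket arrays, drawn from 2 to 4 arrays per point. Zic1 and Gap43 are high in Purkinje arrays at P3 and P7 and low from P14 on, and Gja1 reaches a mean of 12.81 in Stellate/Basket arrays at P56.

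The cell types were also compared at each shared age. At P14 (n = 3 Purkinje, 4 Stellate/Basket), the kinase Nrk was 185-fold higher in Purkinje cells (log2 7.53 ± 0.54, SE), followed by Tmem255a (7.02) and Id2 (6.78), while Zic1 (-7.43), Btbd11 (-7.29) and the histone methyltransferase family member Prdm8 (-6.84) were lower. At this age Xist, expressed from the inactive X chromosome, was between 6.47 and 6.59 in the 3 Purkinje arrays and between 12.8 and 12.9 in the 4 Stellate/Basket arrays, so the cell types also differed in this level. Smpx (5.90 ± 0.43), Stk17b (5.60) and the thrombin receptor F2r (5.54) led at P21 (n = 4 and 3), against Cnr1 (-6.91 ± 0.44), Btbd11 (-6.59) and Prdm8 (-6.36). Leading genes at P28 (n = 4 and 4) were Grik1 (5.12 ± 0.46), the transcription factor Bcl11a (5.09) and Nell1 (4.93), against Cnr1 (-7.20 ± 0.41), Cnpy1 (-6.97) and Zic1 (-6.46). At P35 (n = 4 and 2) they were F2r (5.78 ± 0.87), Stk17b (5.39) and Rasl11b (5.32), against Cnr1 (-6.53 ± 0.50), Btbd11 (-6.33) and Prdm8 (-5.87).

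At P56 (n = 4 and 2) the leading genes changed. Atl1 (4.96 ± 0.55), the heparan sulfate sulfotransferase Hs6st2 (4.43) and Cep76 (4.20, and 2.80 without Stellate/Basket P56 replicate 3) led in Purkinje cells, and the astrocyte gap junction gene Gja1 (-7.15 ± 1.16), Fam107a (-7.13) and the protease inhibitor Timp4 (-6.77) in Stellate/Basket arrays. Interneuron markers differed by a median of -4.45 at P14, with 9 of 9 lower in Purkinje cells, and by -0.15 at P56, with 1 lower and 1 higher. Purkinje markers differed by a median of 3.78 at P14 and 0.95 at P56. The counts were 2327 at P14 (1151 higher in Purkinje cells), 2355 at P21 (1190), 2884 at P28 (1461), 1985 at P35 (1024) and 3599 at P56 (2582). After quantile normalization the share higher in Purkinje cells at P56 was 57.7% in place of 71.7%, and with array weights 1766 genes were called at that age.

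**Figure D3:**
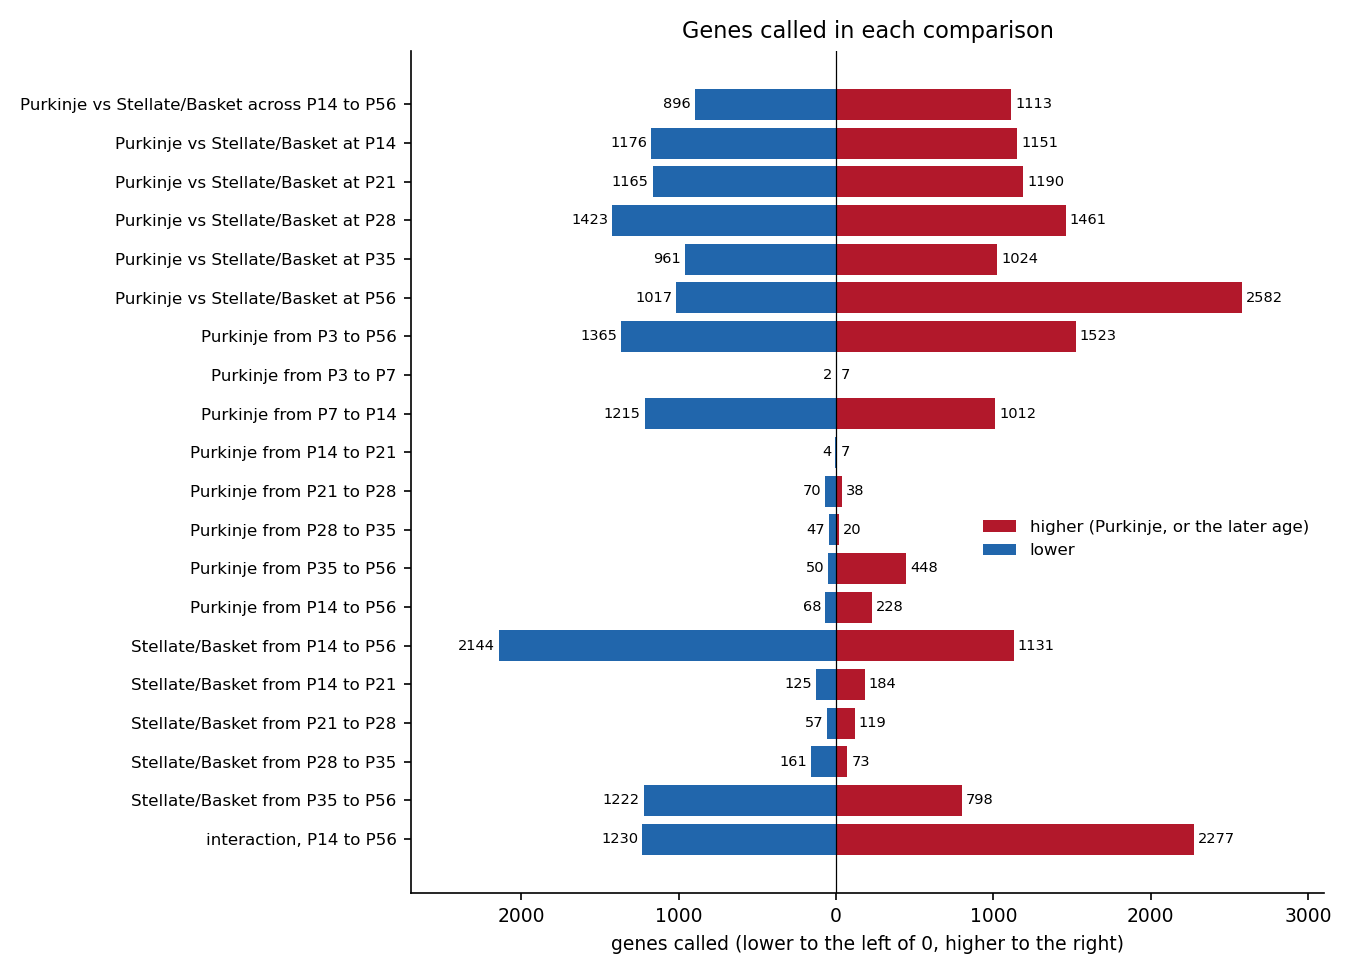
Number of genes called lower (bars to the left of 0) and higher (bars to the right) in each of the 20 comparisons, by limma with an adjusted p under 0.05 and a log2 difference of at least 1. Purkinje cells have 2227 called genes in the step from P7 to P14 and 9 from P3 to P7, and Stellate/Basket cells have 2020 from P35 to P56.

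A second question was how Purkinje cells change from P3 (n = 3) to P56 (n = 4). Gng13 (1419414_at), a G protein gamma subunit, rose from 5.23 ± 0.18 to 12.92 ± 0.20 (SD), a 206-fold increase (log2 7.68 ± 0.39, SE; adjusted p = 1.70e-16). Ppp1r17 (1449240_at) rose by 6.72 ± 0.49, the sodium channel subunit Scn4b by 5.79 ± 0.30 and the potassium channel subunit Kcnab1 by 5.69 ± 0.44, and Aldoc, the metabolic enzyme that marks Purkinje cell stripes, by 5.69 ± 0.32. Zic1 (1423477_at) fell by 7.09 ± 0.45 and the cell cycle inhibitor Cdkn1c by 6.85 ± 0.25. Doublecortin, Dcx (1418139_at), a microtubule protein of immature neurons, fell by 6.34 ± 0.29 (adjusted p = 1.18e-17) and the growth cone protein Gap43 (1423537_at) by 6.14 ± 0.18 (adjusted p = 4.43e-22). Stk17b, Cep76, Nrk, Doc2b and Clmn completed the 10 leading increases (log2 5.69 to 6.63), and Cnpy1, Cd24a, Prkcb, Dpysl3, Enc1 and Glra2 the 10 leading decreases (-6.08 to -6.50). By the rule for naming, these 20 genes were taken only from those where every array of 1 age lay above every array of the other. Called were 2888 genes, 1523 higher and 1365 lower at P56. Over all 7 ages, 4511 genes changed by the F test, of which 1394 had their highest mean at P3, 841 at P7, 357 at P14, 187 at P21, 461 at P28, 124 at P35 and 1147 at P56. With P14 as the first age, 1053 genes changed by the F test.

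All 13 measured Purkinje markers rose (median 4.47; camera adjusted p = 6.72e-15, and 0.00318 with an estimated correlation), among them Car8 (4.75, and 3.04 without Purkinje P3 replicate 3). Beside them, markers of other neurons fell. 8 of 9 interneuron markers fell (median -3.47; camera adjusted p = 4.45e-10, and 0.00103 with an estimated correlation), with Tfap2b at -5.87, the neuronal gap junction gene Gjd2 at -5.57 and Kit at -4.21. 4 of 6 Golgi and unipolar brush cell markers fell (median -2.24; camera adjusted p = 2.10e-04, and 0.00293 with an estimated correlation), including the neuropeptide Sst (-4.73), Lgi2 (-4.57) and the glycine transporter Slc6a5 (-2.59). 6 of 14 granule cell markers fell (median -0.91; camera adjusted p = 2.70e-05, and 0.00294 with an estimated correlation), with Neurod1 at -4.62. Of the astrocyte and Bergmann glia markers 6 of 12 fell and 1 rose (median -1.29), and this list was not called (camera adjusted p = 0.161, and 0.6 with an estimated correlation), except by camera with the preset correlation in a fit of the compared ages alone. Across genes, which are not independent replicates, the Purkinje P3 means correlated with r = 0.963 with Stellate/Basket P14 and r = 0.875 with Purkinje P14.

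Neurite growth and immature neuron genes fell, with 15 of 20 lower and none higher (median -2.41; camera adjusted p = 1.18e-16, and 2.55e-04 with an estimated correlation), among them Cd24a (-6.41) and Dpysl3 (-6.29). Genes of mGluR1, calcium store and protein kinase C signalling rose, 8 of 12 (median 3.19; camera adjusted p = 3.17e-08, and 0.0148 with an estimated correlation), with the ryanodine receptor Ryr1 at 4.39 and Car8, which binds the inositol trisphosphate receptor, at 4.75. Potassium channel genes rose, with 8 of 20 higher and 2 lower (median 0.36; camera adjusted p = 0.00327, and 0.00948 with an estimated correlation), among them Kcna1 (3.53) and the calcium-activated channel Kcnma1 (1.66). Axon guidance genes fell, 16 of 49 lower and 5 higher (median -0.33; camera adjusted p = 2.10e-04, and 0.00318 with an estimated correlation), with Sema6d at -4.53 and Ephb1 at -3.74 against Epha5 at 4.46. Clock genes rose, 6 of 16 higher and 1 lower (median 0.64; camera adjusted p = 2.92e-04, and 0.0204 with an estimated correlation). Their leading members were Dbp (3.85), Hlf (2.32) and Rora (2.98), a nuclear receptor that is also on the Purkinje marker list. Ribosomal protein genes fell (10 of 24; median -0.97; camera adjusted p = 1.29e-08, and 0.0623 with an estimated correlation), with Rpsa at -2.46. Cholesterol synthesis genes fell (5 of 16; median -0.73; camera adjusted p = 0.00499, and 0.0716 with an estimated correlation), with Hmgcs1 at -2.22. Cell cycle genes fell (7 of 20, 2 higher; median -0.56; camera adjusted p = 0.0237, and 0.364 with an estimated correlation), with Rrm2 at -3.31 and Top2a at -2.80. Counts of called members were the same in these lists when adjusted over the list alone. All of these lists changed between the same ages as the interneuron markers.

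Most of this change lay in the step from P7 to P14 (n = 3 and 3). Gng13 rose by 7.17 ± 0.41 (SE; adjusted p = 8.93e-15), Stk17b by 5.68 and Cep76 by 5.20. Zic1 fell by 7.19 ± 0.48, the cell surface protein Cd24a by 6.32 and Btbd11 by 6.27. Called were 2227 genes, 1012 higher and 1215 lower at P14. Of the 1012, 787 (77.8%) were also called higher in Purkinje than in Stellate/Basket cells at P14, against 66.6 expected. Of the 1215, 824 (67.8%) were also called lower in Purkinje cells at P14, against 81.75 expected. Both comparisons use the same Purkinje P14 arrays, so their calls are not independent. The genes of this step therefore cannot be taken as a change of Purkinje cells alone. Over this step 11 of 13 Purkinje markers rose (median 2.56), 9 of 9 interneuron markers fell (median -2.77), 4 of 6 Golgi and unipolar brush cell markers fell and 13 of 20 neurite growth genes fell (median -1.43).

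From P3 to P7 (n = 3 and 3) few genes passed. Nrk rose by 3.10 ± 0.58 (SE; adjusted p = 0.0257), the calmodulin-binding Purkinje marker Pcp4 by 2.12 and Aldoc by 1.81, and Prr3 fell by 1.28. Called were 9 genes, 7 higher and 2 lower, with 610 genes at an unadjusted p under 0.05. Without Purkinje P3 replicate 2 the count was 1, without P7 replicate 1 it was 49, and without P7 replicate 3 it was 2. None of the 4 named genes was called without P3 replicate 2 or without P7 replicate 3. Without P3 replicate 3, Nrk, Pcp4 and Aldoc were not called (2.29, 1.42 and 1.57), and without P7 replicate 2 Aldoc was not (1.64). A fit of these ages alone called 0 genes by limma, with 854 at an unadjusted p under 0.05.

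From P14 to P21 (n = 3 and 4), the orphan receptor Gpr176 rose by 4.20 ± 0.37 (SE; adjusted p = 3.04e-08), the copine Cpne8 by 3.45 and Zic1 by 2.17 (adjusted p = 0.0498). Iah1 fell by 1.80, the sterol regulator Insig1 by 1.48 and the pigment enzyme Dct by 1.18. Called were 11 genes, 7 higher and 4 lower. The count was 4 without any one of P14 replicates 1, 2 and 3, and 17, 6, 7 and 5 without P21 replicates 1, 2, 3 and 4 in turn. Of the 6 named genes, Gpr176 alone was called without each array in turn. Another split of the same arrays called 12.

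From P21 to P28 (n = 4 and 4), Pdxdc1 rose by 1.87 ± 0.30 (SE), the lipid phosphatase Sgpp2 by 1.87 ± 0.27 and the potassium channel subunit Kcng4 by 1.80 ± 0.39. The ubiquitin ligase Lnx1 fell by 2.70 ± 0.52, the sodium pump regulator Fxyd7 by 2.47 ± 0.37 and Mpped2 by 2.44 ± 0.54. Called were 108 genes, 38 higher and 70 lower. The count was 257, 47, 44 and 51 without P21 replicates 1, 2, 3 and 4 in turn, and 62 without P28 replicate 1. Kcng4 was not called without P21 replicate 2 (1.53), nor Mpped2 without P21 replicate 3 (-2.36) or P28 replicate 1 (-1.84). Another split of the same arrays called 161.

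From P28 to P35 (n = 4 and 4), the heat shock protein Hspa1b rose by 2.57 ± 0.33 (SE), the G protein subunit Gng4 by 2.44 ± 0.64 and the seipin gene Bscl2 by 2.01 ± 0.37. Cpne8 fell by 2.87 ± 0.56, the growth factor binding protein Igfbp6 by 1.85 ± 0.37 and the polyamine enzyme Sat1 by 1.57 ± 0.28. Called were 67 genes, 20 higher and 47 lower. The count was 20 without P28 replicate 1, 110 without P28 replicate 3, and 151, 133, 13 and 22 without P35 replicates 1, 2, 3 and 4 in turn. Gng4 was not called without any one of P28 replicates 1, 3 and 4 and P35 replicates 1, 3 and 4 (2.02 to 2.47), nor Cpne8 without P35 replicate 3 (-2.45) or 4 (-2.44), nor Igfbp6 without P35 replicate 4 (-1.64). A split that grouped P28 replicates 1 and 2 with P35 replicates 3 and 4 called 573.

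From P35 to P56 (n = 4 and 4), Slc45a3 rose by 3.34 ± 0.38 (SE), the zinc finger gene Zfp383 by 3.22 ± 0.46 and the glycosyltransferase Gcnt2 by 3.19 ± 0.48. The synaptic protein Clstn1 fell by 2.39 ± 0.32, the Ras exchange factor Rasgrf1 by 2.22 ± 0.37 and Bscl2 by 2.02 ± 0.37. Called were 498 genes, 448 higher and 50 lower. The count was 299, 244, 822 and 841 without P35 replicates 1, 2, 3 and 4 in turn, 748 without P56 replicate 2 and 213 without P56 replicate 4. With the upper end of each array's values as a covariate, 64 genes were called.

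Between P14 (n = 3) and P56 (n = 4), Purkinje cells changed less. Etl4 (1426880_at) rose by 3.78 ± 0.56 (SE; 13.8-fold; adjusted p = 5.59e-05), the integrin subunit Itgav (1452784_at) by 3.30 ± 0.44 and the protocadherin Pcdh20 (1424701_at) by 2.48 ± 0.30. Cpne8, Slc45a3, Zfp383, Sgpp2 and Gpr176 completed the 8 leading increases (2.40 to 2.92). The actin-binding thymosin Tmsb10 (1437185_s_at) fell by 2.99 ± 0.76 (adjusted p = 0.00838) and Clstn1 by 2.48 ± 0.35. The endoplasmic reticulum protein Rtn3 (1418101_a_at) fell by 2.63 ± 0.23 (adjusted p = 7.61e-09). Nell2, Tsks, Dct, Basp1 and Tubb2b completed the 8 leading decreases (-2.41 to -1.72). Called were 296 genes, 228 higher and 68 lower, and 186 without P14 replicate 3. With P35 as the last age 107 genes were called, 33 higher and 74 lower, so the share higher was 30.8% in place of 77.0%. Tubb2b was not called without any one of the P14 replicates or of P56 replicates 1, 2 and 4 (-1.40 to -1.83).

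None of the 29 lists was called between P14 and P56 in Purkinje cells by camera after adjustment, and 4 had an unadjusted p under 0.05. Those 4 were the synaptic vesicle genes (median 0.12; adjusted p = 0.117), GABA-A receptor subunits (0.15; 0.15), neurite growth genes (-0.40; 0.15) and axon guidance genes (-0.18; 0.332). Camera called 4 lists with P35 as the last age, ribosomal protein genes (median -0.42, against 0.02 to P56), oxidative phosphorylation (-0.34) and neurite growth genes (-0.34) lower and GABA-A receptor subunits (0.19) higher. Neurite growth genes were also called lower to P56 after quantile normalization (-0.35), with a filter of log2 above 7 (-0.40) and with the 90th percentile of each array as a covariate (-0.43). Single members passed the test. Basp1 (-1.78), Tubb2b (-1.72) and Dpysl3 (-1.66) fell among the neurite growth genes. Pcdh20 and Cdh11 (2.02) rose among the cadherins, the adhesion molecule Cntn3 by 1.99 and the GABA-A subunit Gabra4 by 1.41. The median, mean and test differed in sign for several lists with small medians, such as the Purkinje markers, with a median of -0.12, a mean of -0.09 and an upward test.

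The same interval was examined in Stellate/Basket cells, from P14 (n = 4) to P56 (n = 2). The P56 arrays correlated across genes, which are not independent replicates, with r = 0.853, where the mean correlation of an array with the others of its group was at least 0.953 in the other groups, and replicate 3 had the lowest 90th percentile of all arrays used (8.55). Tmem255a (1436948_a_at) rose by 6.29 ± 0.37 (SE; 78.4-fold; adjusted p = 2.52e-14). Gja1 (1437992_x_at), a gap junction protein of astrocytes, rose from 6.68 ± 1.98 to 12.81 ± 0.31 (SD; adjusted p = 1.02e-04), the astrocyte water channel Aqp4 by 5.79 ± 0.58, the transcription factor Ebf1 by 5.87 ± 0.48 and Ppp1r17, a Purkinje marker, by 5.68 ± 0.55. Prdm8 (1455925_at) fell by 6.80 ± 0.18 (adjusted p = 3.90e-23), the receptor phosphatase and interneuron marker Ptprk (1423278_at) by 5.85 ± 0.29 and Gap43 (1423537_at) by 5.52 ± 0.21. Clmn, Itih3 and Itgb8 completed the 8 leading increases (5.80 to 5.97), and Sla, Cdc42ep3, Sgk1, Tmem178 and Enc1 the 8 leading decreases (-5.24 to -6.10). Called were 3275 genes, 1131 higher and 2144 lower at P56. After quantile normalization the share higher was 43.8% in place of 34.5%. Over the 5 ages 4185 genes changed by the F test, 1401 of them highest at P14, 590 at P21, 564 at P28, 343 at P35 and 1287 at P56. With P35 as the last age 966 genes were called between P14 and P35, 662 of them shared with the P56 comparison, and 1432 by the F test, and with array weights 1505 were called between P14 and P56.

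Markers of other cells moved with age in these arrays. 11 of 12 astrocyte and Bergmann glia markers rose (median 3.33; camera adjusted p = 1.36e-09, and 0.04 with an estimated correlation), including Gdf10 (4.70) and the glutamate transporter Slc1a3 (3.93). 8 of 13 Purkinje markers rose (median 1.94; camera adjusted p = 6.06e-05, and 0.214 with an estimated correlation), with Calb1 at 5.56, Gng13 at 4.68 and Car8 at 4.66. 8 of 9 interneuron markers fell (median -4.37; camera adjusted p = 3.54e-10, and 0.00141 with an estimated correlation), with Lypd6 at -4.81 and Kit at -4.38. Without Stellate/Basket P56 replicate 1 the Purkinje markers had a median of 0.96 and were not called as a list, and without replicate 3 it was 3.38. The medians of the glial, Purkinje and interneuron markers were 2.25, 0.98 and -0.86 with P35 as the last age, each called.

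Together with these markers, neurite growth and immature neuron genes fell, 13 of 20 lower and 1 higher (median -1.80; camera adjusted p = 1.84e-09, and 0.00648 with an estimated correlation), with Dcx at -5.08 and Dpysl3 at -4.77. Synaptic vesicle genes fell, 10 of 27 lower and 1 higher (median -0.72; camera adjusted p = 1.45e-04, and 0.106 with an estimated correlation), among them Syn3 (-3.32) and Stx1a (-2.81). Voltage-gated calcium channel genes fell, 7 of 16 lower and 1 higher (median -0.19; camera adjusted p = 0.013, and 0.106 with an estimated correlation), with Cacna1e at -4.53 and Cacna2d3 at -4.45. Sodium channel genes fell, 5 of 10 lower (median -1.18; camera adjusted p = 0.0219, and 0.373 with an estimated correlation), with Scn3b at -3.59, and 2 rose, among them Scn4b (3.74). Genes of mGluR1 signalling rose, 7 of 12 higher and 1 lower (median 1.49; camera adjusted p = 0.0108, and 0.368 with an estimated correlation), with Car8 shared with the Purkinje markers. Cholesterol synthesis genes fell (5 of 16; median -0.85; camera adjusted p = 0.0219, and 0.215 with an estimated correlation), with Mvd at -1.96, and so did oxidative phosphorylation genes (6 of 29; median -0.08; camera adjusted p = 0.034, and 0.598 with an estimated correlation), with Ndufv1 at -1.53. Adjusted over the list alone, 2 mGluR1 signalling genes were lower, and the other counts were the same. Between P14 and P35, neurite growth (median -1.13), synaptic vesicle (-0.22), calcium channel (-0.64) and cholesterol synthesis genes (-1.002) were called lower by camera, while mGluR1 signalling (-0.12), sodium channels (-0.62) and oxidative phosphorylation (-0.05) were not called. Endothelial and mural markers (0.29) and immediate early and stress genes (0.45) were then called higher, and ribosomal protein (-0.30) and perineuronal net and neurofilament genes (-0.20) lower. Sodium channels (-0.35), oxidative phosphorylation (-0.07) and cholesterol synthesis (-0.80) were not called with the 90th percentile of each array as a covariate. Without Stellate/Basket P56 replicate 1, mGluR1 signalling (0.41) and cholesterol synthesis (-0.62) were not called, and the medians of synaptic vesicle genes, sodium channels, calcium channels and oxidative phosphorylation were -1.23, -2.75, -0.94 and -0.48. Without replicate 3, sodium channels (0.48), calcium channels (-0.26) and oxidative phosphorylation (0.11) were not called, and the medians of synaptic vesicle genes and mGluR1 signalling were -0.28 and 2.35. Oxidative phosphorylation was at -0.15 without Stellate/Basket P14 replicate 3 and not called without P14 replicate 4 (-0.03). Ndufv1 was at -2.46 without P56 replicate 1 and at -0.59, not called, without replicate 3. The Stellate/Basket P56 group held both the Purkinje markers and the low interneuron markers beside each of these lists.

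From P14 to P21 (n = 4 and 3), glial transcripts rose in the Stellate/Basket arrays. Gja1 rose by 4.97 ± 1.03 (SE; adjusted p = 0.003), the transcription regulator Id4 by 4.66 ± 0.51 and the lipoprotein Apoe by 4.16, while Ndrg1 fell by 3.70, Ly6d by 2.79 and Isoc1 by 2.49. Of the astrocyte and Bergmann glia markers, 8 of 12 rose (median 2.05). Called were 309 genes, 184 higher and 125 lower.

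From P21 to P28 (n = 3 and 4), the lysosomal protease Ctss rose by 2.99 ± 0.29 (SE), Ctxn3 by 2.69 and the stress response transcription factor Nfe2l2 by 2.66. Rec8, Mia and Amn fell by 2.40, 2.22 and 2.07. Called were 176 genes, 119 higher and 57 lower, and a fit of these ages alone called 73.

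From P28 to P35 (n = 4 and 2), Cd24a rose by 2.48 ± 0.52 (SE), Dus2 by 2.22 and the peptidase Trhde by 2.17. Cyp4v3 fell by 3.29 ± 0.41, Atad2b by 3.06 and the zinc transporter Slc39a12 by 2.25. Called were 234 genes, 73 higher and 161 lower. Without Stellate/Basket P35 replicate 1 the count was 86 and without replicate 2 it was 508. Without replicate 1, Cd24a (2.28), Dus2 (1.498), Atad2b (-2.05) and Slc39a12 (-0.87) were not called, and without replicate 2 Slc39a12 was at -3.62. A fit of these ages alone called 0 genes by limma, with 2564 at an unadjusted p under 0.05.

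From P35 to P56 (n = 2 and 2), the cytochrome P450 Cyp4v3 rose by 4.22 ± 0.47 (SE), Ebf1 by 4.13 and F2r by 4.08. Prdm8 fell by 5.99 ± 0.21, the kainate receptor subunit Grik3 by 5.66 and Cd24a by 5.23. Over this step 7 of 9 interneuron markers fell (median -2.82), 5 of 13 Purkinje markers rose (median 1.43) and 4 of 12 glial markers rose (median 1.07). Called were 2020 genes, 798 higher and 1222 lower, with 3056 without Stellate/Basket P56 replicate 1 and 316 with array weights. F2r was not called without P35 replicate 1 (2.54) or P56 replicate 1 (2.81). A fit of these ages alone called 0 genes by limma, with 2036 at an unadjusted p under 0.05.

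The last question was whether the change from P14 to P56 differs between the cell types, tested as the Purkinje change minus the Stellate/Basket change. Prdm8 (1455925_at) changed by 0.36 in Purkinje and by -6.80 in Stellate/Basket cells, a difference of 7.16 ± 0.24 (SE; adjusted p = 4.92e-20). Differences were also positive for Cdc42ep3 (6.46), Hs6st2 (6.20), Sla (6.20), the kinase Sgk1 (5.74), Ptprk (5.57), Tmem178 (5.44) and Btbd11 (5.37). Id4 (1450928_at) changed by -0.90 in Purkinje and 5.56 in Stellate/Basket cells, a difference of -6.46 ± 0.76 (adjusted p = 1.57e-07). Clmn (-5.96), Tmem255a (-5.95), Itih3 (-5.89), Nrk (-5.80), the integrin Itgb8 (-5.69), Calb1 (-5.61) and Ppp1r17 (-5.53) followed. Called were 3507 genes, 2277 with a positive and 1230 with a negative difference. Each of these differences uses the Stellate/Basket P56 arrays, with their raised Purkinje and low interneuron markers. The median difference over all genes was -0.15. With P35 as the last age 462 genes were called, 333 of them shared, and with array weights 2017.

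By list, interneuron markers had positive differences, 8 of 9 (median 4.25; camera adjusted p = 1.30e-09, and 0.00204 with an estimated correlation). Negative differences were found for the Purkinje markers (8 of 13; median -2.27; camera adjusted p = 8.52e-04, and 0.303 with an estimated correlation) and the astrocyte and Bergmann glia markers (11 of 12; median -3.50; camera adjusted p = 1.23e-07, and 0.0704 with an estimated correlation). Beside these markers, 11 of 27 synaptic vesicle genes had positive differences (median 0.82; camera adjusted p = 6.09e-06, and 0.0522 with an estimated correlation), with the small GTPase Rab3c at 3.23 and Syn3 at 3.21. So did neurite growth genes, 10 of 20 with 2 negative (median 1.37; camera adjusted p = 9.84e-06, and 0.0522 with an estimated correlation), led by Dcx (5.20), where 11 were positive when adjusted over the list alone. Sodium channel genes had 6 positive and 2 negative of 10 (median 1.58; camera adjusted p = 0.0117, and 0.303 with an estimated correlation), among them the channel subunits Scn3b (3.84) and Scn2a (2.93). Calcium channel genes had 7 positive and 1 negative of 16 (median 0.04; camera adjusted p = 0.0267, and 0.179 with an estimated correlation), led by Cacna1e (4.41). Adhesion molecules had 9 positive of 29 (median 0.28; camera adjusted p = 0.0188, and 0.231 with an estimated correlation), led by L1cam (3.22), and genes of GABA synthesis and transport 5 of 10 (median 0.89; camera adjusted p = 0.0486, and 0.321 with an estimated correlation), led by the vesicular transporter Slc32a1 (2.41) and the enzyme Gad2 (1.52). Slc32a1 was at 4.07 without Stellate/Basket P56 replicate 1 and at 0.74, not called, without replicate 3.

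Some of these list differences depended on single arrays, on the last age or on the upper range of the arrays. With the 90th percentile of each array as a covariate, sodium channels (0.26), calcium channels (0.18), adhesion molecules (0.09) and GABA synthesis and transport (0.30) were not called, and mGluR1 signalling (-2.08) was. Without Stellate/Basket P56 replicate 1 the Purkinje markers (-0.94) were not called, and the medians of sodium channels, calcium channels, adhesion molecules and neurite growth genes were 2.89, 0.71, 0.64 and 2.06. Without replicate 3, GABA synthesis and transport (0.497), sodium channels (-0.08), calcium channels (0.12) and adhesion molecules (0.0054) were not called, and the medians of Purkinje markers, synaptic vesicle and neurite growth genes were -3.71, 0.48 and 0.66. GABA synthesis and transport was also not called without Purkinje P14 replicate 2 (0.86), Purkinje P56 replicate 4 (0.82) or Stellate/Basket P14 replicate 1 (0.85). Nor was it called with a block of replicate number (0.85) or with the mean of a gene's probe sets (0.34). The small median of the calcium channels changed sign without Purkinje P14 replicate 3 (-0.06), Purkinje P56 replicate 2 (-0.10) or Stellate/Basket P14 replicate 4 (-0.04), and was 0.13, 0.22 and 0.10 without Purkinje P14 replicate 2, Purkinje P56 replicate 3 and Stellate/Basket P14 replicate 1. Adhesion molecules were at 0.12 without Purkinje P14 replicate 2 and 0.18 without Purkinje P56 replicate 1. When P35 was the last age, the medians of the interneuron, glial and Purkinje markers were 0.72, -1.78 and -1.18 and those of synaptic vesicle, neurite growth, calcium channel and adhesion genes 0.30, 0.99, 0.67 and 0.22, each called. Sodium channels (0.19) and GABA synthesis and transport (0.19) were then not called, and erythrocyte markers (-0.48), oxidative phosphorylation (-0.23) and cholesterol synthesis (0.67) were.

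Shared changes between P14 and P56 were counted directly. Higher at P56 in both cell types were 56 genes, where 14.8 would be shared if the lists were independent, and lower in both were 21, against 8.34. Genes higher in Purkinje and lower in Stellate/Basket cells numbered 33, against 28.0, and 8 showed the reverse, against 4.40. The Stellate/Basket P56 arrays held raised Purkinje markers (mean 8.33 at P14 and 10.87 at P56), and their source stays open. These counts therefore cannot be taken as the overlap of the 2 cell types alone. Across genes, which are not independent replicates, the changes in the 2 cell types correlated with Pearson's r = -0.02. Gap43, Dcx and Dpysl3 fell in Stellate/Basket cells between P14 and P56, with log2 changes of -5.52, -5.08 and -4.77. In Purkinje cells they fell over another window, P3 to P56, with -6.14, -6.34 and -6.29. From P14 to P56 the neurite growth list in Purkinje cells had a median of -0.40 and was not called. The Purkinje P3 and Stellate/Basket P56 arrays also held markers of other cells. These falls therefore cannot be taken as a change shared by the 2 cell types. With P35 as the last age r was 0.23, and 7 genes were higher and 13 lower in both cell types. Without Purkinje P14 replicate 3, 36 genes were higher in both. Without Stellate/Basket P56 replicate 1 r was -0.12 and without replicate 3 it was 0.10.

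**Figure D4:**
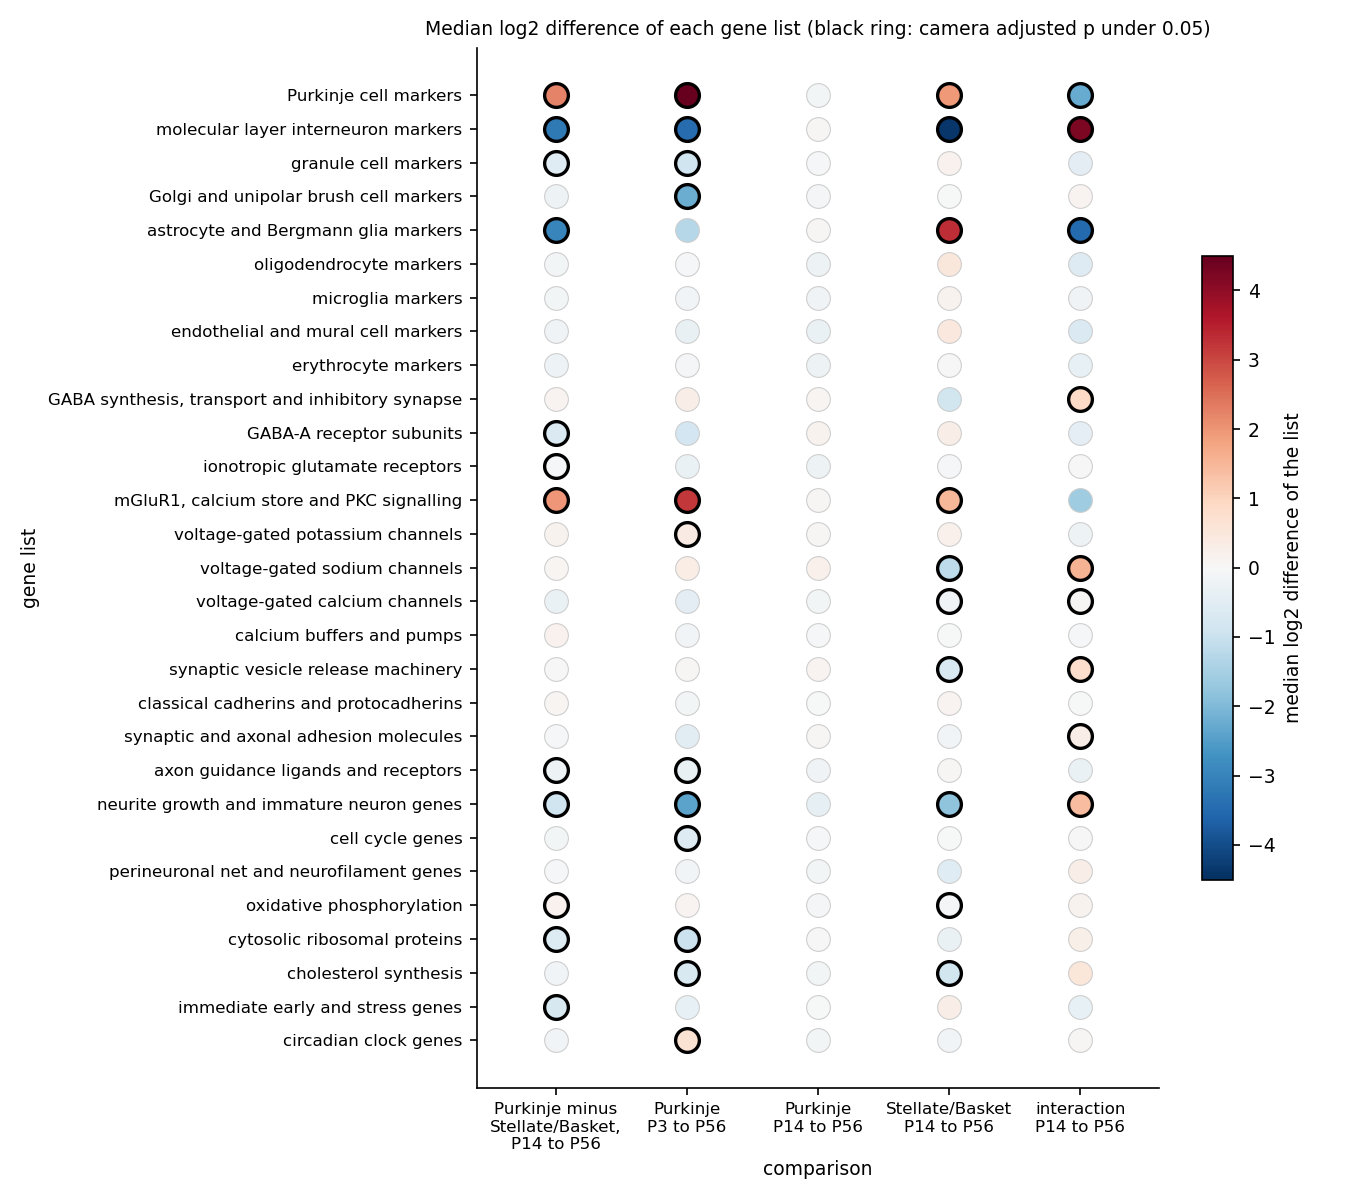
Median log2 difference (colour) of the 29 gene lists (vertical) in the 5 main comparisons (horizontal), with a black ring where camera gave an adjusted p under 0.05 with the preset correlation. Neurite growth genes are ringed in 4 of the 5 comparisons, with a median of -2.41 in Purkinje cells from P3 to P56.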

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

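The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts of splits were planned before.

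In groups of 4 arrays, 204 values of markers and lists were examined for 1 array far from the others, and 12 passed Dixon's critical value at the 95% level for the gap divided by the range. Chance gives about 1 in 20. 7 of the 12 lay in Purkinje P28. Replicate 1 of that group stood apart in the means of oligodendrocyte markers (7.29 against 6.75 to 6.83, ratio 0.847), potassium channels (0.863), cadherins (0.831) and perineuronal net genes (0.924), and in Calb1 (0.877). Its replicate 2 stood apart in synaptic vesicle genes (0.918) and Pcp2 (0.888). Purkinje P21 replicate 2 was apart in interneuron markers (6.74 against 6.05 to 6.16, ratio 0.831), and Purkinje P56 replicate 1 in adhesion molecules (0.847). Stellate/Basket P14 replicate 1 was apart in interneuron markers (0.928) and sodium channels (0.87), and replicate 3 in calcium channels (0.915). Over the named genes, 128 of 1812 values (7.06%) passed, where chance gives 5%.

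The change from P14 to P56 differed between the cell types in 3507 genes by limma's test of the difference. With P35 as the last age 462 genes were called, 333 of them shared. The Stellate/Basket P56 group holds 2 arrays, with raised Purkinje and low interneuron markers. These differences to P56 therefore cannot be taken as those of the 2 cell types alone. Prdm8 changed by 0.36 in Purkinje and -6.80 in Stellate/Basket cells, a difference of 7.16. The same test gave 6.46 for Cdc42ep3 (0.77 and -5.69), 6.20 for Hs6st2 (1.58 and -4.62), 6.20 for Sla (0.09 and -6.10), 5.74 for Sgk1 (0.31 and -5.44), 5.57 for Ptprk (-0.28 and -5.85), 5.44 for Tmem178 (0.11 and -5.33) and 5.37 for Btbd11 (0.57 and -4.81). In the other direction it gave -6.46 for Id4 (-0.90 and 5.56), -5.96 for Clmn (0.00 and 5.97), -5.95 for Tmem255a (0.34 and 6.29), -5.89 for Itih3 (0.03 and 5.91), -5.80 for Nrk (-0.41 and 5.40), -5.69 for Itgb8 (0.11 and 5.80), -5.61 for Calb1 (-0.05 and 5.56) and -5.53 for Ppp1r17 (0.15 and 5.68).

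The Stellate/Basket P56 arrays held Purkinje cell transcripts and few interneuron transcripts, with Calb1 at 13.2 and 12.1 and Kit at 5.35 and 6.86 in replicates 1 and 3. A swap of labels with Purkinje P56 is argued against, since the highest Purkinje P56 array lay at -3.02 relative to the Stellate/Basket P35 mean of the interneuron markers. RNA of Purkinje cells in these samples may be a source, although the sort used soma size: 95.5% of 66 abundant Purkinje-enriched genes lay at least 1 log2 unit above Stellate/Basket P14, with 100% in replicate 1 and 74.2% in replicate 3. At P21, P28 and P35 the share was 37.9%, 57.6% and 45.5%, and Zic1, low in Purkinje cells from P14 on, was still at 10.6 and 11.6 in the P56 arrays. The 66 genes were chosen in part for low values in Stellate/Basket P14, the baseline they were scored against. That choice favours a rise at each later age. A change of Stellate/Basket cells with age stays open and was not tested.

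The Purkinje P3 and P7 arrays held transcripts that Stellate/Basket arrays held at P14 and later Purkinje arrays did not. All 52 abundant Stellate/Basket-enriched genes (100%) lay within 3 log2 units of Stellate/Basket P14, with a median of -0.38, and Zic1, which is on the granule cell list, was between 11.8 and 12.5. Markers outside that set did not all match Stellate/Basket P14. The Golgi and unipolar brush cell markers had a mean of 8.40 at P3 and 8.37 at P7, against 6.51 in Stellate/Basket P14. RNA of interneurons in these samples is a candidate source, although the sort used fluorescence and soma size. Whether it was added to a constant amount of Purkinje RNA cannot be told apart from age: the Purkinje markers lay at -3.41 relative to Purkinje P14, and unevenly, with Calb1 at 12.60 and Gng13 at 6.61 in P7 replicate 3, against at least 13.5 and 13.2 at P14. Within P3, Calb1 was at 4.46 in replicate 3 against 11.68 and 11.04 in replicates 1 and 2, with Kit at 9.73 against 9.78 and 9.37. This gap lies between arrays of the same age and rests on 1 array. Expression of the Stellate/Basket-enriched genes by young Purkinje cells, a difference of age, stays open and was not tested.

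Astrocyte and Bergmann glia markers rose in Stellate/Basket arrays from P14 to P21, with 8 of 12 called and Gja1 between 11.4 and 11.9 at P21. The P14 arrays already differed, with Gja1 at 5.29, 4.96, 9.25 and 7.23 in replicates 1, 2, 3 and 4. Gja1 was also at 9.35 in Purkinje P28 replicate 1, against 5.1 to 5.17 in the others of that group. These gaps lie between arrays of the same age. The highest median change among the oligodendrocyte, microglia, and endothelial and mural lists was 0.19 (the others 0.082 and -0.003) against 2.05. These lists cannot decide on a lower share of the main cell type, since RNA of glial or Purkinje cells would lower it without raising them. From P14 to P21 the mean of the interneuron markers went from 10.30 to 9.73 and that of the Purkinje markers from 8.33 to 9.12. A change in the distribution of values between arrays is argued against, since the median of the astrocyte and Bergmann glia markers was 2.08 after quantile normalization. RNA of glial cells in these samples, despite the sort by fluorescence, stays open: the 8 called markers are the pattern itself, so their number cannot decide it. A change of the sorted cells with age also stays open and was not tested.

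Other splits of the same arrays were counted, the real split included. Such counts weigh chance alone and do not part cell type or age from other structure of the arrays. Chance is argued against, at a share under 0.05 not adjusted over the comparisons, where the real split alone reached its count. This holds among 35 splits for the cell type difference at P14 (2327, highest other 1497), P21 (2355, 1459) and P28 (2884, 60), for Purkinje P3 to P56 (2888, 2129), P35 to P56 (498, 344) and P14 to P56 (296, 228), and for Stellate/Basket P14 to P21 (309, 81) and P21 to P28 (176, 60). At P14 the cell types also differed in Xist (6.47 to 6.59 in Purkinje, 12.8 to 12.9 in Stellate/Basket arrays), so within that age the splits do not part the 2, and with Xist as a covariate over all groups 2225 were called. Chance is likewise argued against among 100 drawn splits for the cell type difference across ages (2009, 860) and for the F test over the 7 Purkinje ages (4511, 2301). Chance cannot be excluded for Purkinje P14 to P21, where 2 of 35 splits reached 11 genes (highest other 12), P21 to P28, where 2 of 35 reached 108 (161), and P28 to P35, where 4 of 35 reached 67 (573). The split that called 573 points to a structure of the samples: it set the 4 arrays with Xist between 6.84 and 7.22 against the 4 with Xist between 10.7 and 11.1, and the same arrays had 90th percentiles between 9.14 and 9.26 against 8.79 to 8.97. The step from P28 to P35 called 68 with Xist and 153 with the 90th percentile as a covariate. The 10 splits of Purkinje P3 to P7 (9, highest other 31; 4 splits as large) and P7 to P14 (2227, 4; 1 split) are too few for a share under 0.05. Apart from the average across ages, comparisons with Stellate/Basket P35 or P56 hold groups of 2 and have no such count.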

How the results depend on the processing

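Alternatives with all 42 columns, the Xist level or the 90th percentile as a covariate, and another first or last age were chosen after the data were seen. No count moved by over 1.5 times with no filter on dim genes, another variance model, a block of replicate number, centring, or Xist as a covariate. The block called 2009 genes for the cell type difference, 2840 for Purkinje P3 to P56 and 3231 for Stellate/Basket P14 to P56. Replicate numbers do not pair the arrays: in 1 of 45 pairs of groups did every same-number correlation exceed 0.1. Where the cause of a move is not given, the cause was not tested. Of 549 called results for named genes, 380 were called the same way under every alternative run for named genes. The changed thresholds and another first or last age were not run for them. Few arrays and dim values limit the folds. At Stellate/Basket P35 and P56 leaving out 1 array leaves 1, assumed to vary like the other groups.

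Each count below stands for its comparison. With a filter of log2 above 7, Purkinje P3 to P7 called 18. Using the mean of a gene's probe sets, the cell type difference called 1332 and that at P28 1914, Purkinje P3 to P7 5, P14 to P21 5, P21 to P28 54, P28 to P35 36, P35 to P56 259 and P14 to P56 137. For Stellate/Basket P14 to P21 it called 189, P21 to P28 92, P28 to P35 114 and P35 to P56 1284, with 24 genes higher and 8 lower in both cell types. In a fit of the compared groups only, with fewer samples, the cell type difference at P56 called 2234, Purkinje P14 to P21 6, P21 to P28 7, P28 to P35 1 and P35 to P56 240, and Stellate/Basket P21 to P28 73. Called by limma in this fit were 0 genes for Purkinje P3 to P7 (854 at an unadjusted p under 0.05), 0 for Stellate/Basket P28 to P35 (2564) and 0 for P35 to P56 (2036).

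Array weights gave 1766 for the cell type difference at P56, 92 for Purkinje P3 to P7, 62 for P14 to P21, 456 for P21 to P28, 329 for P28 to P35 and 461 for P14 to P56. They gave 1505 for Stellate/Basket P14 to P56, 148 for P28 to P35, 316 for P35 to P56, 2017 for the difference between changes, and 26 genes higher in both. Quantile normalization gave 298 for Purkinje P35 to P56, with 77.5% higher in place of 89.96%. It moved the share higher at P56 between cell types from 71.7% to 57.7%, in Purkinje P28 to P35 from 29.9% to 45.3%, and positive differences between changes from 64.9% to 54.6%. Centring moved the share higher in Purkinje P14 to P56 from 77.0% to 88.6%. The median difference between changes over all genes, -0.15, was -0.09 centred and -0.07 after quantile normalization, which ended the list calls of ionotropic glutamate receptors and oxidative phosphorylation between the cell types, oxidative phosphorylation and cholesterol synthesis in Stellate/Basket cells, and GABA synthesis and calcium channels in the difference between changes. The filter of log2 above 7 ended the first 4 of these and those of cell cycle genes in Purkinje cells, sodium and calcium channels in Stellate/Basket cells, and GABA synthesis, sodium and calcium channels in the difference between changes. The fit of the compared groups ended those of ionotropic glutamate receptors between the cell types and of mGluR1 signalling, sodium and calcium channels and oxidative phosphorylation in Stellate/Basket cells. In this fit the medians stayed as in the main fit, at 1.49 for mGluR1 signalling, -1.18 for sodium channels and -0.19 for calcium channels.

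With no minimum fold, more genes pass by construction: 9277 for the cell type difference, 4071 at P14, 4529 at P21, 7774 at P28, 3373 at P35 and 8191 at P56. Purkinje P3 to P56 then had 6039, P7 to P14 3694, P21 to P28 494, P28 to P35 233, P35 to P56 4258 and P14 to P56 2464. Stellate/Basket P14 to P56 had 6339, P14 to P21 669, P21 to P28 363, P28 to P35 405 and P35 to P56 3389, the difference between changes 6361, the F tests 9838 and 7082, and 180 genes were higher and 183 lower in both. At an adjusted p under 0.01, Purkinje P3 to P7 had 1, P14 to P21 5, P21 to P28 40, P28 to P35 13, P35 to P56 279 and P14 to P56 175. Stellate/Basket P21 to P28 had 95 and P28 to P35 80, with 30 genes higher and 11 lower in both.

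All 42 columns gave 20 for Purkinje P3 to P7 and 394 for Stellate/Basket P28 to P35. Every call of the 40 arrays was shared with a fit of the 42 columns on the same genes in the 20 comparisons. With the 90th percentile as a covariate, the cell type difference at P56 called 2040, Purkinje P3 to P7 20, P28 to P35 153 and P35 to P56 64, and r across genes was 0.13. With P14 as the first age the Purkinje F test called 1053. With P35 as the last age, Purkinje called 107 (43 shared), Stellate/Basket 966, the difference between changes 462 and the Stellate/Basket F test 1432, r was 0.23, and 7 genes were higher and 13 lower in both.

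Leaving out each array in turn moved some counts by over 1.5 times. Purkinje P3 to P7 ran from 1 without P3 replicate 2 to 49 without P7 replicate 1, and was 2 without P7 replicate 3. P14 to P21 ran from 4 without any one P14 replicate to 17 without P21 replicate 1, and was 6, 7 and 5 without P21 replicates 2, 3 and 4. P21 to P28 ran from 44 without P21 replicate 3 to 257 without P21 replicate 1, and was 47 and 51 without P21 replicates 2 and 4 and 62 without P28 replicate 1. P28 to P35 ran from 13 without P35 replicate 3 to 151 without P35 replicate 1, and was 133 and 22 without P35 replicates 2 and 4, and 20 and 110 without P28 replicates 1 and 3. P35 to P56 ran from 213 without P56 replicate 4 to 841 without P35 replicate 4, and was 299, 244 and 822 without P35 replicates 1, 2 and 3 and 748 without P56 replicate 2. Purkinje P14 to P56 ran from 186 without P14 replicate 3 to 413 without P56 replicate 2. Stellate/Basket P28 to P35 ran from 86 to 508, without P35 replicates 1 and 2, and P35 to P56 from 1756 without P35 replicate 1 to 3056 without P56 replicate 1. Genes higher in both ran from 36 without Purkinje P14 replicate 3 to 80 without Stellate/Basket P56 replicate 3. The correlation r ran from -0.12 to 0.10, without Stellate/Basket P56 replicates 1 and 3. Within 1.5 times, the cell type difference at P56 ran from 2457 to 5061, the difference between changes from 2747 to 4846 and Stellate/Basket P14 to P56 from 2997 to 4213, each lowest without Stellate/Basket P56 replicate 3 and highest without replicate 1.

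6 named results reversed, all in Stellate/Basket P14 to P56 or the difference between changes. Without Stellate/Basket P56 replicate 1, the change of Cldn5 was -0.045 (highest 4.02). Without replicate 3, Gabrb2 was 0.0061 (lowest -4.93), Gria2 0.070 (lowest -6.00), Ier2 0.11 (lowest -2.98) and Hspa1b 0.13 (lowest -2.58), and the difference between changes of Gria2 was -0.14 (highest 5.93).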

Other observations

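The values of Xist, of Eif2s3y and of single arrays given here were chosen after the data were seen.

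Calcium buffers and pumps did not move one way as a list, but single members did. Parvalbumin, Pvalb, a fast calcium buffer, rose by 5.03 ± 0.43 (SE) in Purkinje cells from P3 (n = 3) to P56 (n = 4) and Calb1 by 4.47 ± 0.94 (2.17 without P3 replicate 3), while the plasma membrane pump Atp2b3 fell by 3.40 ± 0.38. Of 13 measured members, 6 rose and 4 fell (median -0.16, mean 0.74, camera adjusted p = 0.201). Between the cell types 5 were higher and 2 lower in Purkinje cells (median 0.18; adjusted p = 0.752), and in Stellate/Basket cells from P14 to P56 5 rose and 3 fell (median -0.02; adjusted p = 0.923).

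Perineuronal net and neurofilament genes moved both ways without a list call. From P3 to P56 the neurofilament heavy chain Nefh rose by 4.49 ± 0.34 in Purkinje cells and the link protein Hapln4 by 3.25 ± 0.25, while the proteoglycans Vcan and Ncan fell by 5.89 ± 0.28 and 3.42 ± 0.21. Perineuronal net and neurofilament genes had 3 higher and 3 lower of 12 (median -0.15; camera adjusted p = 0.82), 4 and 3 between the cell types (median -0.07, mean 0.20, adjusted p = 0.948), and 4 and 4 in Stellate/Basket cells from P14 to P56 (median -0.53; adjusted p = 0.374). In that list the matrix protein Tnr was lower in Purkinje cells (log2 -3.63 ± 0.13) and fell in Stellate/Basket cells by 4.62 ± 0.32, beside the fall of the interneuron markers. Cadherins and protocadherins went both ways, with 5 higher and 6 lower of 23 in Purkinje cells from P3 to P56 (median -0.14; adjusted p = 0.272), among them Pcdh15 (-3.95) and Cdh4 (-3.86). Between the cell types the cadherin list had 4 higher and 2 lower (median 0.08; adjusted p = 0.835).

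Oligodendrocyte, microglia, endothelial and mural, and erythrocyte markers had no list call in any of the 5 main comparisons, although alternatives called some of these lists. Between the cell types their medians were -0.13, -0.11, -0.19 and -0.25 (camera adjusted p = 0.218, 0.218, 0.107 and 0.424). In Stellate/Basket cells from P14 to P56 they were 0.52, 0.18, 0.46 and 0.01 (adjusted p = 0.103, 0.528, 0.0838 and 0.959), with Cnp up by 2.16 (1.88, not called, without P56 replicate 3) and Olig1 by 1.90 among the oligodendrocyte markers. In Purkinje cells from P3 to P56, Olig1 rose by 3.30 and Mbp fell by 1.78, and limma called 0 of 9 microglia, 0 of 10 endothelial and mural, and 0 of 3 erythrocyte markers, with 1, 2 and 1 at an unadjusted p under 0.05.

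All 40 arrays are labelled male. Xist, expressed from the inactive X chromosome, was above log2 10 in 27 arrays, and in 26 of these the Y-linked gene Eif2s3y was at or under 6. In 13 arrays the opposite held, and 1 array had both above these levels. Xist was above 10 in 13 of 25 Purkinje and 14 of 15 Stellate/Basket arrays. By age it was above 10 in 2 of 3 Purkinje arrays at P3 and at P7, 0 of 3 at P14, 3 of 4 at P21 and 2 of 4 at P28, P35 and P56, and in all Stellate/Basket arrays but 1 at P35. Over the arrays Xist ran from 6.38 to 12.9 and Eif2s3y from 4.15 to 9.24.

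In Purkinje P3 replicate 3, Calb1 was at 4.46, Car8 at 5.39 and Pcp2 at 6.46, against 11.04 and 11.7 for Calb1, 10.2 and 10.9 for Car8 and 8.81 and 9.93 for Pcp2 in the other arrays of that group. Slc32a1, the vesicular GABA transporter, was at 11.9 in Stellate/Basket P56 replicate 1 and 8.57 in replicate 3.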
